A study of Rattus norvegicus with 30 samples.

How the data were processed

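Liver RNA of 3 kinds of male animal was measured on 30 arrays. Chimeric mice whose livers carry rat hepatocytes gave 14 arrays, 7 on control diet and 7 on a diet with 1000 ppm PB. Crl:CD(SD) rats, an outbred stock called SD rats here, gave 4 arrays on each diet, and rats with a knockout of CAR gave 4 on each diet. Per the series title, PB is phenobarbital and CAR is the constitutive androstane receptor, the nuclear receptor encoded by Nr1i3. Feeding lasted 7 days. The labels call the arrays biological replicates and give 4 to 7 animals per dose, and groups and replicate numbers were taken from the sample titles.

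Per the labels' protocols, livers were kept in RNAlater, RNA was prepared with Isogen and RNeasy kits, and 100 ng was labelled with Cy3 by a 1-colour kit. Per the file headers, each array was a rat gene expression design, 028279, with 62976 spots, read by Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09 and a grid annotated to rn4. The intensity values of the deposited scanner files are the scanner software's processed signal, background-subtracted and detrended within an array but not scaled between arrays, per the file headers; the files also hold each spot's median and local background intensity. The authors' series matrix holds log2 values on a scale not given in the sources used here. Set against the scanner files, each of its columns had a correlation across probes of 1 with log2 of the processed signal. A correlation does not depend on an offset per array, so the value subtracted from each array was not established. Its column medians are kept with the array values. It served only as an alternative.

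Of the spots, 4259 control spots were left out, spots marked as outliers by the scanner software were set missing, and the spots of a probe were averaged, which left 30367 probes. No non-control spot was saturated on any array (0 over all arrays). The values tested were log2 of the processed signal minus each array's 75th percentile of it. Probes were named through their transcript accession in a table of rat RefSeq genes made for assembly GRCr8, used for names only. In all, 18004 probes matched 15170 symbols, and 12363 probes had no match, 3989 of them designed to Ensembl transcripts. Unmatched probes were tested as unnamed transcripts. Cyp2b1 and Mki67 were not among the matched names and are not analysed here. Cyp3a1 appears under its present name Cyp3a23-3a1. For 2599 symbols with over 1 probe, the probe with the highest mean over the 16 rat arrays was used, which gave 26912 genes or unnamed transcripts.

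A gene was tested where its probe was well above background, by the scanner software's own test, on at least 75% of the arrays of at least 1 of the groups compared. Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and files were read with the R package data.table (1.17.8). The 16 rat arrays made 1 fit for the PB response of each rat model, the difference between these responses, and the difference between the models on control diet. The 14 chimeric arrays made another fit, and comparisons of chimeric mice with SD rats used all 30 arrays. Every adjusted p of a gene is limma's, with Benjamini-Hochberg adjustment over the genes tested, and the threshold was 0.05. Errors of log2 fold changes are standard errors, and those of levels are SDs between arrays. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean over all replicates minus the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. A difference of responses takes such a group at the same floor and is given as "at least" where a lower level there would make the difference larger, and without a size otherwise. That bound was added after the data were seen. Where only some arrays of a group measured a gene, their number is given, and the size rests in part on signals not well above background. Brightness over background, not read depth, limits what these arrays show, and the number of arrays limits the precision.

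The 30 gene lists cover xenobiotic metabolism (CAR/PXR-responsive cytochrome P450 and partner genes, conjugation enzymes, drug and bile acid transporters, AhR-responsive and NRF2-responsive genes) and intermediary metabolism (PPAR-alpha and fatty acid oxidation, lipogenesis, cholesterol synthesis, bile acid synthesis and FXR, glucose metabolism). Others cover growth and stress (cell cycle, growth arrest and early growth, unfolded protein response, acute phase, interferon-responsive, circadian clock) and liver zones, sex and identity (male-predominant, female-predominant, pericentral, periportal, fetal and preneoplastic, nuclear receptor genes). The marker lists are of cell types (hepatocyte, macrophage and Kupffer cell, T, NK and B cell, neutrophil, endothelial, stellate cell and fibroblast, cholangiocyte and erythroid markers). Some lists share genes: 9 of the 27 P450 list genes on the array and 8 of the 28 NRF2 list genes also stand in another list. Among the cell type marker lists, 3 of the 17 hepatocyte markers and 1 of the 16 cholangiocyte markers stand in another list, and the other 6 marker lists share none. Each list was tested against all other genes with camera (limma) at its preset correlation of 0.01, adjusted over the lists with at least 5 tested members in a comparison, then again with an estimated correlation, and with fry, which tests a list's genes on their own. Calls within a list are given over all genes and adjusted over the list alone.

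Genes named in the text follow a rule: per comparison of 2 groups, up to 8 largest increases and 6 largest decreases past the threshold in genes whose groups do not overlap and which were well above background on every array of the brighter group, with a symbol other than a placeholder. Per difference of responses, up to 5 in each direction were taken. To these came up to 3 members of each list by adjusted p and a fixed set led by Nr1i3, Cyp2b2, Cyp3a23-3a1, Por and Ugt2b1. The text leaves out part of the list members, and 1 gene that the rule names is not reported here. Genes of a set of 5 or fewer are also named, and those were chosen after their values were seen. The design, the lists, this rule, the threshold and most alternatives were fixed before the data were examined.

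The arrays lay on 4 slides with 2 rows of 4 places. Slide 1 held the 7 chimeric controls and 1 chimeric PB array, slide 2 the other 6 chimeric PB arrays, slide 3 the SD rats and slide 4 the CAR KO rats, with control diet in row 1 and PB in row 2 on slides 3 and 4. Slides 1 and 2 shared one scan day and slides 3 and 4 another. The chimeric comparison was repeated with slide as a block, and within slide 1 alone. Both estimates rest on the 1 PB array of slide 1. For the rat comparisons the slide is the model, so a slide block leaves the responses as they are, and slide and model cannot be told apart on control diet. Each diet of the rats lay in its own row, so row and PB cannot be told apart within a rat model.

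Alternatives were normexp background correction (offset 50), quantile normalization, median centring, the authors' series matrix, no filter or a stricter filter on dim probes, and the mean of a gene's probes. Further ones were other sets of arrays in the fit, array weights, a trended and robust spread, stricter thresholds, the replicate number as a block, leaving out each array in turn, and the slide as a fixed or random block. Normexp was to use mean spot intensities; it used the median intensities, which are the ones the scanner files hold. The tests were checked on simulated data with 200 changed genes among the genes tested. The simulated noise was independent between genes and held no slide, row or array effect, so recovery in the real data may differ. At a 2-fold change the tests recovered 79.1% of changed genes in SD rats, 79.1% in CAR KO rats and 77.6% in chimeric mice. They recovered 61.2% for the difference between CAR KO and SD responses, 35.8% for that between chimeric and SD responses, 85.1% for CAR KO against SD rats and 80.6% for chimeric mice against SD rats. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.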

Results

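Gene expression was measured in livers of chimeric mice with rat hepatocytes, SD rats and CAR KO rats fed a control diet or 1000 ppm phenobarbital (PB) for 7 days. PB is a barbiturate that raises drug-metabolising enzymes in liver, in large part through CAR. Per its title, the study set out to compare hepatic effects of PB between animal models, and this part holds the rat liver arrays. The share of probes well above background was 64.1% ± 0.606 in SD controls and 59.8% ± 0.858 in SD rats on PB (SD, n = 4 each). It was 65.9% ± 1.11 and 62.7% ± 1.81 in CAR KO rats (SD, n = 4 each) and 55.3% ± 2.47 and 52.96% ± 1.7 in chimeric mice (SD, n = 7 each). Scanner signal at the 75th percentile averaged 443 ± 20.4 in SD controls, 506 ± 23.9 in CAR KO controls and 280 ± 39.3 in chimeric controls, so a gene of low signal was measured less often in chimeric livers. Pairs of arrays within a rat group correlated across probes above 0.991, and pairs within the chimeric groups at 0.966 or above.

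In SD rats PB raised the cytochrome P450 genes Cyp2b21 and Cyp2b2. Cyp2b2 rose 16.4-fold (log2 fold change 4.03 ± 0.138, adjusted p = 7.63e-10), from a level of 2.95 ± 0.18 to 6.98 ± 0.335 on the log2 scale (SD, n = 4 each), and a second probe of the gene rose by 6.96 ± 0.289. Cyp2b21 was well above background on 1 of 4 control arrays and on all 4 PB arrays, and rose by 8.24 ± 0.532. Abcc3, an export pump for conjugated drugs and bile acids, rose at least 24.8-fold, since no control array measured it. Aldh1a1, which oxidises retinaldehyde, rose 20.7-fold. The carboxylesterase genes Ces2c and Ces2j rose 13.2-fold and 5.51-fold, the glucuronosyltransferase Ugt2b1 9.35-fold and the phosphatase gene Dusp13b 7.08-fold, with adjusted p of at most 0.00111 for each.

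Among 17002 genes tested in SD rats, 732 changed on PB, 426 higher and 306 lower, and 136 of them changed at least 2-fold (95 higher, 41 lower). Each diet lay in its own row of the slide, so row and PB cannot be told apart within the SD arrays. Of the 25 P450 and partner genes tested, 11 rose and none fell (13 rose adjusted over the list alone), with a median log2 fold change of 0.77. Camera placed the list above other genes, adjusted p = 5.02e-14, and 0.00739 with an estimated correlation. The list's risers included Cyp3a23-3a1 (2.10 ± 0.193, adjusted p = 2.57e-05), the P450 reductase Por (1.57 ± 0.175, adjusted p = 0.000159), the epoxide hydrolase Ephx1 (2.01 ± 0.163) and the aflatoxin aldehyde reductase Akr7a3 (2.21 ± 0.242). Cyp3a2 stood at 0.87 ± 0.377 and did not pass the test (adjusted p = 0.215). Of 37 conjugation enzymes 14 rose and 1 fell (17 and 3 adjusted over the list alone; camera adjusted p = 3.71e-09, and 0.00544 with an estimated correlation). Gsta4 rose by 0.86 ± 0.0782, and the hydroxysteroid sulfotransferase Sult2a1 was the member that fell (-1.30 ± 0.259, adjusted p = 0.0119). Of 25 NRF2-responsive genes 11 rose and none fell (14 and 0 adjusted over the list alone; camera adjusted p = 3.93e-13, and 0.00109 with an estimated correlation), among them glutathione reductase Gsr (1.06 ± 0.119) and malic enzyme Me1 (1.72 ± 0.349). The transporters went both ways, with 4 higher and 4 lower of 21 (7 and 5 adjusted over the list alone; camera adjusted p = 0.56; median -0.02, mean 0.30). Of 6 AhR-responsive genes 2 rose (2 and 1 lower adjusted over the list alone; camera adjusted p = 0.0415, and adjusted p = 0.133 with an estimated correlation).

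Of 26 cholesterol synthesis genes 12 rose and none fell (19 and 0 adjusted over the list alone), with a median log2 fold change of 0.64. Msmo1, a sterol demethylase, rose by 1.38 ± 0.2 (adjusted p = 0.00158). Camera gave the list adjusted p = 1.03e-14, and adjusted p = 0.133 with an estimated correlation. Of 48 cell cycle genes 8 rose and 1 fell (19 and 2 adjusted over the list alone), with a median of 0.48. Camera gave adjusted p = 1.43e-10, and adjusted p = 0.224 with an estimated correlation. Gins1, part of the replicative helicase, rose by 0.97 ± 0.105 (adjusted p = 0.000132) and the mitotic kinesin Kif11 by 1.03 ± 0.186 (3 of 4 control arrays measured it). The replication factor Mcm10 fell (-1.69 ± 0.379, adjusted p = 0.0229), and cyclin D1 (Ccnd1) stood at 0.20 ± 0.234 (adjusted p = 0.684). Of 27 growth arrest and early growth genes 2 rose (3 adjusted over the list alone; camera adjusted p = 0.321), among them Gadd45b, a stress-inducible gene (1.78 ± 0.203, adjusted p = 0.000186). Of 34 interferon-responsive genes 2 rose (2 adjusted over the list alone; median 0.17; camera adjusted p = 9.58e-05, and adjusted p = 0.294 with an estimated correlation). Lipogenesis gave 2 higher of 23 (3 adjusted over the list alone; camera adjusted p = 0.0685).

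Decreases in SD rats included the metallothionein genes Mt2A (-2.31 ± 0.49, adjusted p = 0.017) and Mt1 (-1.99 ± 0.453, adjusted p = 0.0247). Others were the copine gene Cpne4 (at least 3.07-fold, measured on no PB array), Tsc22d1 (-1.68 ± 0.334) and the flavin monooxygenase Fmo1 (-1.67 ± 0.329). Of 42 PPAR-alpha and fatty acid oxidation genes 6 fell and none rose (10 lower adjusted over the list alone; camera adjusted p = 3.13e-06, and adjusted p = 0.224 with an estimated correlation). Cpt1a, which carries fatty acids into mitochondria, fell by 1.23 ± 0.269 (adjusted p = 0.0204). Of 22 glucose metabolism genes 1 rose and 2 fell (1 and 12 adjusted over the list alone; median -0.33; camera adjusted p = 6.06e-05, and adjusted p = 0.133 with an estimated correlation). Of 12 pericentral genes 2 fell (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.00405, and adjusted p = 0.269 with an estimated correlation), among them ornithine aminotransferase Oat (-1.24 ± 0.186). Of 17 periportal genes 3 fell (4 adjusted over the list alone; camera adjusted p = 9.72e-05, and adjusted p = 0.133 with an estimated correlation). Of 17 hepatocyte markers 3 fell (4 adjusted over the list alone; median -0.10; camera adjusted p = 0.00847, and adjusted p = 0.269 with an estimated correlation). The T, NK and B cell markers had no member past the test over all 17002 genes in limma (0 of 14, 3 lower adjusted over the list alone; median -0.25; camera adjusted p = 0.0415, and adjusted p = 0.555 with an estimated correlation).

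The remaining lists did not pass camera in SD rats, and their counts adjusted over the list alone are in brackets. Bile acid synthesis gave 1 lower of 18 [2 higher, 4 lower], the unfolded protein response 1 lower of 25 [2 lower], and acute phase genes 2 higher and 1 lower of 28 [2 and 2; median -0.05, mean 0.02]. Nuclear receptors gave 1 lower of 22 [2 lower], male-predominant genes 1 lower of 20 [4 lower] and female-predominant genes 2 lower of 14 [1 higher, 2 lower]. Camera adjusted p of these lists ran from 0.0565 to 0.56. Limma called 0 of 12 clock genes, 0 of 11 fetal genes, 0 of 18 macrophage markers, 0 of 13 endothelial, 0 of 17 stellate cell, 0 of 10 cholangiocyte [1 higher] and 0 of 7 erythroid markers, with camera adjusted p from 0.0565 to 0.626. Over all genes, 3420 had an unadjusted p under 0.05. With only the 8 SD arrays in the fit 186 genes were called, 176 of them among the 732 in the same direction, and with all 30 arrays in 1 fit 200 were, 178 of them among the 732. With no filter on dim probes 3520 were called. The share of higher genes, 58.2% here, was 69.4%, 77% and 83.3% in these 3 settings. The count of 732 fell to 396 without SD PB 3, 453 without SD control 1 and 484 without SD control 4. Mt2A missed the threshold without SD PB 3 or control 1 (adjusted p 0.0517 to 0.0566), Mt1 without SD PB 1 or 3 or control 1, 2 or 4 (0.0507 to 0.0738). Mcm10 missed it without SD PB 1, 2 or 3 or control 1 or 2 (0.0505 to 0.0619).

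**Figure D1:**
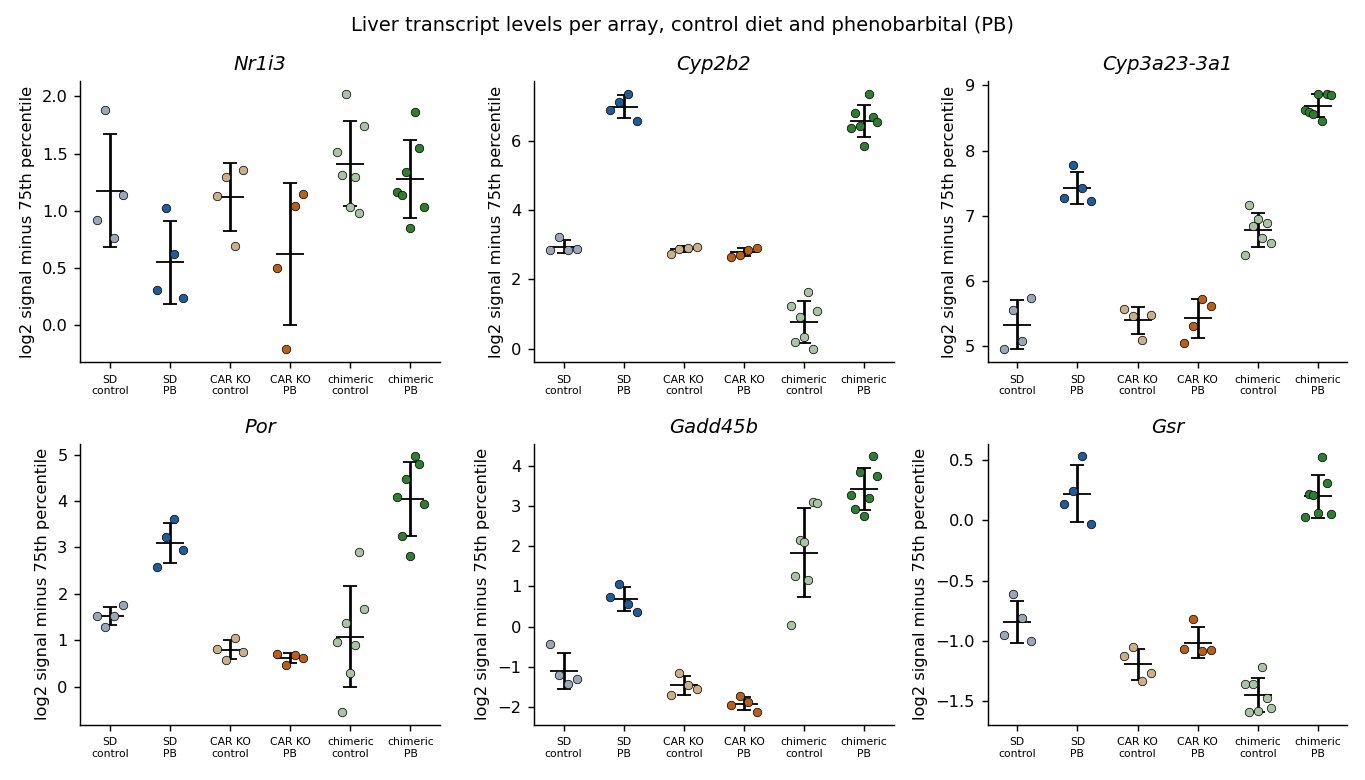
Log2 level relative to each array's 75th percentile (vertical axis) for Nr1i3, Cyp2b2, Cyp3a23-3a1, Por, Gadd45b and Gsr, with 1 point per array in the 6 groups and the mean ± SD of each group. Cyp2b2 averages 6.98 in SD rats and 6.57 in chimeric mice on PB, and 2.78 in CAR KO rats on PB.

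The knockout comparison starts from the targeted gene. The probe of Nr1i3 used here read 0.92, 1.88, 0.76 and 1.14 on the SD control arrays, 0.31, 1.03, 0.62 and 0.24 on the SD PB arrays. It read 1.13, 1.30, 0.69 and 1.35 on the CAR KO control arrays, and 0.50, -0.21, 1.04 and 1.15 on the CAR KO PB arrays. CAR KO and SD controls differed by -0.05 ± 0.304 (adjusted p = 0.907, n = 4 each). A second probe of the gene, well above background on all 16 rat arrays, differed by 0.09 ± 0.338 between these controls (fitted with the probes of this gene alone). The place of either probe relative to the deleted part of the gene is not given in the sources used here, and a probe outside the deleted part checks nothing about the labels. The PB response of the gene was -0.63 ± 0.303 in SD rats and -0.50 ± 0.303 in CAR KO rats, neither past the test (adjusted p 0.267 and 0.443), and the second probe gave -0.67 ± 0.331 and -0.41 ± 0.331.

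In CAR KO rats Cyp2b2, Cyp3a23-3a1, Por, Gadd45b and Ugt2b1, which PB raised in SD rats, did not pass the test. Cyp2b2 stood at 2.87 ± 0.0865 on control diet and 2.78 ± 0.117 on PB (SD, n = 4 each; log2 fold change -0.09 ± 0.138, adjusted p = 0.803). The responses were 0.03 ± 0.193 for Cyp3a23-3a1 (adjusted p = 0.965), -0.18 ± 0.176 for Por (adjusted p = 0.652), -0.45 ± 0.204 for Gadd45b (adjusted p = 0.292) and 0.70 ± 0.406 for Ugt2b1 (adjusted p = 0.417). Of 17543 genes tested 36 changed, 9 higher and 27 lower, and 14 changed at least 2-fold (5 higher, 9 lower). Here too each diet lay in its own row of the slide, so row and PB cannot be told apart. The transcription factor Zbtb16 fell 7.61-fold (2 of 4 PB arrays measured it; adjusted p = 0.0149). The liver phosphofructokinase-2 gene Pfkfb1 fell by 1.17 ± 0.173, the actin-binding gene Ablim3 (-1.197 ± 0.179) fell, and the flavin monooxygenase Fmo2 fell by 1.36 ± 0.23. Zfp786, a zinc finger gene, rose at least 6.38-fold, and the mitochondrial lyase Clybl and Htatip2 rose by 0.48 ± 0.0808 and 0.39 ± 0.0706. Further decreases were Paqr8 (at least 1.94-fold), the olfactory receptor gene Or6b2 (at least 1.97-fold) and the cell cycle inhibitor gene Cdkn2a (-0.60 ± 0.102, adjusted p = 0.0356).

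In CAR KO rats conjugation enzymes had a median of 0.12 and NRF2-responsive genes of 0.20, and both stood above other genes by camera (adjusted p = 2.08e-05 and 1.15e-05, and 0.0223 for both with an estimated correlation). In limma 0 of 39 and 0 of 26 passed over all genes, with 4 higher, and 8 higher and 2 lower, adjusted over the list alone. The P450 list had 0 of 24 past the test (6 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.228; median -0.00305, mean 0.11). PPAR-alpha (median -0.17), lipogenesis (0.13), male-predominant (-0.26), periportal (0.10) and interferon genes (0.06) passed camera with adjusted p of 0.00534, 0.00534, 0.00694, 0.0175 and 0.0462, but had adjusted p = 0.694, and 0.808 for interferon, with an estimated correlation. None of their genes passed over all genes in limma (0; 0, 3 higher and 1 lower, 5 lower, 2 higher and 1 lower, and 0 adjusted over the list alone). Cholesterol synthesis (median 0.08, camera adjusted p = 0.122) and cell cycle genes (median -0.08, camera adjusted p = 0.639) had 0 of 26 and 0 of 48 past the test. In this comparison 2856 genes had an unadjusted p under 0.05.

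The CAR KO calls rested on few arrays. Without CAR KO PB 2 the count was 7, and it was 11, 12, 15 and 17 without control 1, PB 4, control 4 and PB 3. With only the 8 CAR KO arrays in the fit limma called 0 genes, with 3086 at an unadjusted p under 0.05. With all 30 arrays in 1 fit 23 were called (14 of the 36), with array weights 325 and with no filter on dim probes 1706. Zbtb16 passed whichever array was left out. Zfp786 missed the threshold without PB 2 (adjusted p = 0.0616), Ablim3 without PB 2 or 4 (0.0512 to 0.0787), Pfkfb1 without PB 2 or control 1 (0.0502 to 0.0738) and Cdkn2a without PB 2 or 4 or control 1, 2 or 4 (0.0516 to 0.122). Clybl, Htatip2, Fmo2, Paqr8 and Or6b2 missed it on leaving out any of 6 to 8 of the 8 arrays (0.0507 to 0.134). The share of higher genes, 25% here, was 41.5% after normexp, 41.2% after quantile normalization and 56.2% after median centring. It was 47.8% with all 30 arrays in 1 fit, 50% with a trended and robust spread and 77.7% with no filter on dim probes.

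The difference between the 2 rat responses was tested directly. Genes that PB raised in SD rats responded less in CAR KO rats: Cyp2b2 by -4.12 ± 0.196 (adjusted p = 9.06e-08), Aldh1a1 by -3.70 ± 0.641, and Ces2c by -2.83 ± 0.387. The differences of Cyp2b21 and Abcc3 passed the test (adjusted p = 0.000677 and 0.00374), and no size is given, since no CAR KO control array measured either gene. Gadd45b (-2.24 ± 0.289), Cyp3a23-3a1 (-2.07 ± 0.274), Por (-1.75 ± 0.249), Ephx1 (-1.45 ± 0.231) and the replication gene Gins1 (-0.95 ± 0.15) also responded less. The adjusted p of each was at most 0.0171 (log2, n = 4 per group). For Ugt2b1 the difference was -2.52 ± 0.575 and did not pass (adjusted p = 0.0754), but it passed without CAR KO PB 1 (-2.96 ± 0.437, adjusted p = 0.00977). Genes with a higher response in CAR KO rats included Cpne4 (by at least 2.01, measured on no SD PB array; adjusted p = 0.0185), Oat (1.61 ± 0.265), the histidine-degrading enzyme Hal (1.07 ± 0.187), Clybl (0.90 ± 0.114) and the steroid dehydrogenase Hsd17b2 (0.86 ± 0.152). The adjusted p of Hsd17b2, 0.0192 here, was 0.0502 to 0.0504 without CAR KO PB 2 or control 4. In all, 95 of 17804 genes differed, 19 higher and 76 lower in CAR KO rats, and 2345 had an unadjusted p under 0.05. With all 30 arrays in 1 fit 39 differed, 35 of them among the 95.

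By list, 8 of 25 P450 and partner genes had a lower response in CAR KO rats (1 higher and 14 lower adjusted over the list alone; median -0.62; camera adjusted p = 5.9e-12, and 0.0376 with an estimated correlation). Lower responses of cholesterol synthesis genes (median -0.56, 0 of 26 past limma's test over all genes, 9 adjusted over the list alone; camera adjusted p = 1.18e-08) had adjusted p = 0.336 with an estimated correlation. Cell cycle genes (median -0.55, 1 of 49 lower, 6 adjusted over the list alone; camera adjusted p = 3.15e-09) had the same adjusted p, 0.336, with an estimated correlation. NRF2-responsive genes (2 lower of 26, 8 adjusted over the list alone; median -0.24) had camera adjusted p = 0.00083, and adjusted p = 0.0724 with an estimated correlation. Periportal genes responded higher (1 of 17, 6 adjusted over the list alone; median 0.43; camera adjusted p = 4.35e-07, and adjusted p = 0.065 with an estimated correlation). Female-predominant genes did so too (0 of 17, 2 adjusted over the list alone; median 0.49; camera adjusted p = 0.00662, and adjusted p = 0.065 with an estimated correlation). Conjugation enzymes, AhR-responsive genes, hepatocyte markers and erythroid markers passed camera (adjusted p 0.0264, 0.0457, 0.0457 and 0.0318) and had adjusted p of 0.185, 0.17, 0.553 and 0.603 with an estimated correlation.

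Across the 16741 genes tested in both rat models, log2 responses correlated at 0.267 (across genes, which are not independent replicates), and 72.1% of 712 genes called in SD rats had the same sign in CAR KO rats. Genes higher in both numbered 3 against 0.122 by independent lists (Fisher's exact test, p = 0.00014), and genes lower in both 3 against 0.452 (p = 0.0101). Both responses came from 1 fit with the same spread per gene, so the lists are not independent. These p values are a description only. The shared genes were named after their values were seen. Higher in both were Zfp786, Htatip2 and an unnamed transcript, and lower in both Myom1, Pfn4 and an unnamed transcript. Clybl fell by 0.42 ± 0.0806 in SD rats and rose in CAR KO rats. Of the 95 genes raised at least 2-fold in SD rats, 78 were tested in CAR KO rats, where their median response was 0.16 against 1.6 in SD rats. In CAR KO rats 1 was called (Zfp786) and 71 had less than 50% of the SD log2 response. The difference was past the test for 34 of them. These genes were selected on the same SD arrays, which by itself makes the SD values high.

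In chimeric mice PB raised Cyp2b21 at least 81.3-fold, since no control array measured it, and Cyp2b2 55.9-fold (log2 fold change 5.80 ± 0.264, adjusted p = 2.13e-09, n = 7 each), from 0.77 ± 0.605 to 6.57 ± 0.455 (SD). Lipoprotein lipase (Lpl) rose at least 41.1-fold, the glucuronosyltransferase Ugt2b7 at least 7.22-fold, the glutathione transferase Gstm3 by 3.91 ± 0.427 and the palmitoyltransferase Zdhhc2 by 3.86 ± 0.206. Abcc3 rose by 3.46 ± 0.366 (5 of 7 control arrays measured it) and Cyp26a1, which degrades retinoic acid, by 3.35 ± 0.451. Vsir, a checkpoint receptor, fell (-4.53 ± 0.55), as did the class II histocompatibility gene RT1-Da (-3.61 ± 0.449) and granzyme B (Gzmb; -3.08 ± 0.411). Each of the 3 was measured on 1 of 7 PB arrays. The histamine receptor Hrh4 fell by 3.26 ± 0.489, the protocadherin Pcdh20 (2 of 7 PB arrays) by 3.08 ± 0.428, and Apol7b fell by 2.998 ± 0.318. A second probe of Apol7b stood at 0.96 ± 0.473. The marker of macrophages Cd68 (-1.38 ± 0.153), glutamine synthetase Glul (-1.78 ± 0.277) and Fmo1 (-1.57 ± 0.118) also fell.

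Limma called 6168 of 14441 genes in chimeric mice, 2794 higher and 3374 lower, with 1866 at least 2-fold (376 higher, 1490 lower). Slide 1 held all controls and 1 PB array and slide 2 the other PB arrays. With slide as a block 158 genes passed the threshold, 102 higher and 56 lower, of which 143 were among the 6168 in the same direction (94 higher, 49 lower). Within slide 1 alone 219 genes passed (173 higher, 46 lower), and with slide as a random block 2561 did (950 higher, 1611 lower). The higher calls had a median log2 fold change of 0.57, and of 0.33 with the slide block, and the lower calls of -0.92 and -0.30. The block estimate comes from PB 1 and the 7 controls, which also entered these calls, so agreement between the 2 estimates is in part built in. Median centring moved the median of all genes by 0.28 on the log2 scale and the share of higher calls from 45.3% to 70.8%, and the slide block moved that median by -0.10.

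With the slide block Cyp2b2 stood at 5.59 ± 0.541 (adjusted p = 0.000126) and Zdhhc2 at 3.77 ± 0.423 (0.00038), both past the test. Cyp2b21 (adjusted p = 9.38e-07), Lpl (0.00013) and Ugt2b7 (0.000233), not well above background on any control array, passed too. Aldh1a1 stood at 2.40 ± 0.247 after 2.39 ± 0.123, Ugt2b1 at 2.36 ± 0.288 after 2.32 ± 0.142, Akr7a3 at 3.22 ± 0.403 after 3.04 ± 0.198 and Cyp3a23-3a1 at 1.84 ± 0.253 after 1.91 ± 0.126. Por rose by 2.97 ± 0.456 over all arrays and stood at 3.01 ± 0.947 with the block (adjusted p = 0.211), Abcc3 at 3.15 ± 0.754 (0.0682), Gstm3 at 3.82 ± 0.886 (0.0596) and Cyp26a1 at 2.69 ± 0.915 (0.262). The P450 list had 15 higher and 0 lower of 25 (16 and 3 adjusted over the list alone; median 0.96; camera adjusted p = 3.77e-08, and 0.0311 with an estimated correlation). With the slide block it had 8 higher (camera adjusted p = 2.18e-16, and 0.00317 with an estimated correlation). Of 38 conjugation enzymes 19 rose and 2 fell (19 and 3 adjusted over the list alone; camera adjusted p = 3.82e-05, and adjusted p = 0.151 with an estimated correlation). With the block 2 were higher (camera adjusted p = 6.68e-06, and adjusted p = 0.0884 with an estimated correlation). Nr1i3 itself stood at -0.14 ± 0.184 (adjusted p = 0.571).

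Of 25 NRF2-responsive genes, which include antioxidant enzymes, 17 rose and 1 fell (18 and 1 adjusted over the list alone; median 1.08; camera adjusted p = 3.77e-08, and 0.0114 with an estimated correlation), and 6 were higher with the slide block (camera adjusted p = 1.04e-13, and 0.000559 with an estimated correlation). The glutathione peroxidase Gpx2 rose by 3.22 ± 0.234 (2.90 ± 0.473 with the block), Me1 by 2.53 ± 0.226 (1.94 ± 0.43) and Gsr by 1.65 ± 0.104 (1.48 ± 0.199), all past the test both ways. The chemokine Cxcl9 rose by 3.07 ± 0.138 (3.08 ± 0.279 with the block). Of 26 cholesterol synthesis genes 18 rose and none fell (18 and 0 adjusted over the list alone; median 0.83; camera adjusted p = 3.02e-06, and adjusted p = 0.217 with an estimated correlation). With the block limma called 0 of them (median 0.40; camera adjusted p = 1.45e-05, and adjusted p = 0.156 with an estimated correlation). Msmo1 stood at 1.28 ± 0.152, and at 1.08 ± 0.303 with the block (adjusted p = 0.143). Of 36 cell cycle genes 22 rose and 4 fell (25 and 4 adjusted over the list alone; median 0.68; camera adjusted p = 6.52e-05, and adjusted p = 0.492 with an estimated correlation). With the block 1 was higher (camera adjusted p = 1.08e-11, and adjusted p = 0.156 with an estimated correlation). It was thymidine kinase Tk1 (1.56 ± 0.125, and 1.33 ± 0.24 with the block, adjusted p = 0.0138). Lipogenesis (11 higher and 2 lower of 23, the same adjusted over the list alone; camera adjusted p = 0.012) and the unfolded protein response (8 higher of 25, the same adjusted over the list alone; 0.0243) had adjusted p of 0.357 and 0.497 with an estimated correlation. Neither passed camera with the block (0.239 and 0.41). Gadd45b rose by 1.59 ± 0.419 and stood at 1.44 ± 0.869 with the block (adjusted p = 0.627).

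With the slide block Vsir stood at -0.93 ± 0.286 (adjusted p = 0.193), RT1-Da at -0.91 ± 0.422 (0.475), Gzmb at -0.86 ± 0.511 (0.614), and Hrh4 at -1.88 ± 0.923 (0.511). Pcdh20 stood at -1.03 ± 0.626 (0.63), Apol7b at -1.11 ± 0.313 (0.14), Cd68 at -0.82 ± 0.26 (0.217) and Glul at -0.93 ± 0.509 (0.569). Fmo1 stayed past the test (-1.60 ± 0.235, adjusted p = 0.0037). All 6 T, NK and B cell markers tested, of 17 on the array, were lower (6 adjusted over the list alone; median -0.95; camera adjusted p = 0.00357, and adjusted p = 0.217 with an estimated correlation). With the block limma called 0 of them (median -0.71; camera adjusted p = 0.0756). Over 14 of these markers, 42.9% of values were well above background in controls and 32.7% on PB. A gene can enter the test through the controls alone, so the count of lower members is in part set by the filter. The livers also hold cells of the mouse host, and how well the rat probes read their RNA was not measured. Cell type marker lists therefore do not measure the number of such cells here. Of 12 macrophage markers 7 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.40; camera adjusted p = 0.046, and adjusted p = 0.357 with an estimated correlation). With the block limma called 0 of them, the median was -0.47 and camera gave adjusted p = 0.0348, and adjusted p = 0.217 with an estimated correlation. Of 7 endothelial markers 2 fell (2 adjusted over the list alone; median -0.19; camera adjusted p = 0.356), and of 15 stellate cell markers 2 rose and 5 fell (3 and 5 adjusted over the list alone; median -0.00901; camera adjusted p = 0.825). Of 7 cholangiocyte markers 2 rose and 2 fell (2 and 3 adjusted over the list alone; median 0.0135, camera's direction lower; adjusted p = 0.87), and of 5 erythroid markers 3 rose (4 adjusted over the list alone; median 0.56; camera adjusted p = 0.117). With the block limma called 0 genes of these 4 lists, and their medians were -0.31, -0.00414, -0.19 (mean 0.09) and 0.21 (camera adjusted p from 0.148 to 0.901). The mean level of the T, NK and B cell list was -4.47 ± 0.124 in chimeric controls and -5.11 ± 0.3 in chimeric mice on PB, and that of the macrophage list -1.18 ± 0.145 and -1.49 ± 0.142 (SD, n = 7 each). Hepatocyte markers averaged 7.01 ± 0.15 and 6.95 ± 0.186 (SD, n = 7 each), with a median log2 fold change of -0.10 (camera adjusted p = 0.482). With the block their median was -0.32 (camera adjusted p = 0.00262, and adjusted p = 0.15 with an estimated correlation). Acute phase genes had a median of -0.23 (camera adjusted p = 0.311), and of -0.62 with the block (camera adjusted p = 5.14e-06, and adjusted p = 0.15 with an estimated correlation).

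**Figure D2:**
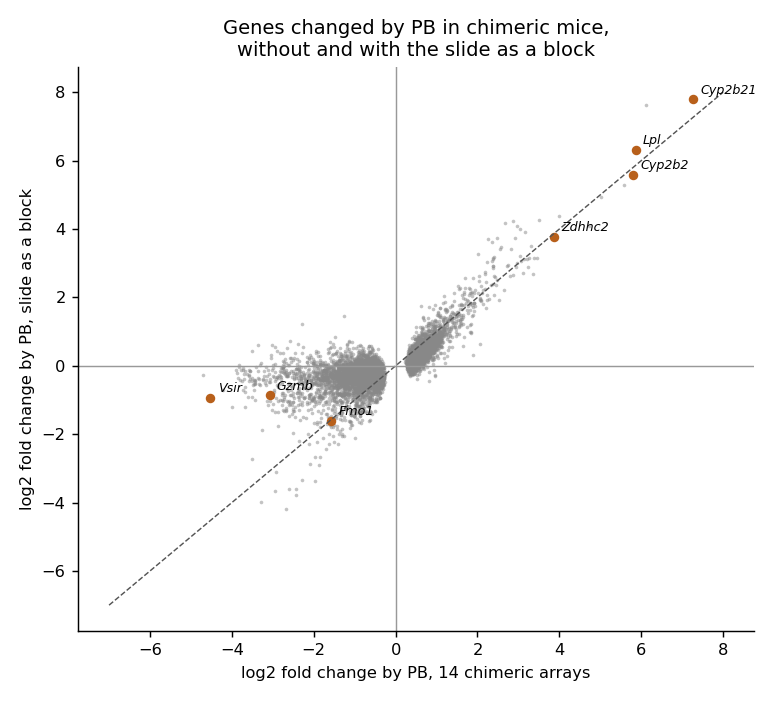
Log2 fold change on PB in chimeric mice from all 14 arrays (horizontal axis) against the same with slide as a block (vertical axis), 1 point per gene called over the 14 arrays. Higher calls have a median of 0.57 and, with the block, 0.33; lower calls have -0.92 and -0.30; both estimates use the 7 controls and PB 1.

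Responses of chimeric mice and SD rats overlapped. Among 14191 genes tested in both, 312 were higher in both against 75.9 by independent lists (Fisher's exact test, p = 2.56e-152), 98 were lower in both against 55.4 (p = 9.75e-10) and 13 were opposite. With the slide block in the chimeric fit, an alternative added after the data were seen, 66 were higher in both against 2.63 (Fisher's exact test, p = 9.28e-82) and 10 lower in both against 0.967 (p = 3.47e-08). Log2 responses correlated at 0.405 across genes, and at 0.554 with the block, and 88.5% of 634 SD calls had the same sign. Of 76 genes raised at least 2-fold in SD rats and tested in chimeric mice, 73 were higher in chimeric mice, 38 with the slide block, with a median response of 1.91, and of 1.94 within slide 1. The others, named after their values were seen, were Inmt (1.499 ± 0.828, adjusted p = 0.16, against 2.34 ± 0.544 in SD rats) and a pair of unnamed transcripts, 1 of which was lower in chimeric mice.

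The difference between the 2 responses was called for 3250 of 17243 genes, 1082 higher and 2168 lower in chimeric mice, with 5440 at an unadjusted p under 0.05. Lpl responded more in chimeric mice by at least 4.17 (log2; adjusted p = 1.51e-06) and Tor4a by at least 1.78 (adjusted p = 5.21e-05), since no chimeric control array measured them. So did A1bg (4.29 ± 0.907), the histamine-forming enzyme Hdc (2.55 ± 0.479) and the telomere-binding gene Ten1 (2.40 ± 0.725). Vsir (-4.36 ± 0.694), the transcriptional inhibitor Id3 (-3.79 ± 0.717), the actin-bundling gene Fscn1 (-3.68 ± 0.706), Lrg1 (-3.37 ± 0.805) and RT1-Da (-3.32 ± 0.584) responded less. With slide as a block 32 genes passed the threshold (20 higher, 12 lower, 19 of them among the 3250 in the same direction), and within slide 1 167 passed. Lpl (adjusted p = 0.00016) and Tor4a (0.00118) were among the 32. A1bg (4.18 ± 1.34, adjusted p = 0.313), Hdc (2.76 ± 0.704, 0.119), Ten1 (2.53 ± 1.07, 0.534), and Vsir (-0.77 ± 0.304, 0.478) were not, nor were Id3 (-0.47 ± 0.552, 0.955), Fscn1 (-0.23 ± 0.453, 0.993), Lrg1 (-2.58 ± 1.17, 0.563) and RT1-Da (-0.62 ± 0.447, 0.833).

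Cyp2b2 responded more in chimeric mice than in SD rats by 1.77 ± 0.347 (adjusted p = 0.000891; 1.56 ± 0.507 with the block, adjusted p = 0.324). For this probe the chimeric controls started lower, at 0.77 against 2.95 in SD controls. On PB its level was 6.57 in chimeric mice and 6.98 in SD rats. The size and direction of the difference hold for the probe used. A second probe of Cyp2b2 rose more in SD rats than the probe used, and its difference between the models was not tested on its own. The difference was -0.19 ± 0.227 for Cyp3a23-3a1 (adjusted p = 0.608) and 1.40 ± 0.587 for Por (adjusted p = 0.0977). Of the lists, NRF2-responsive genes (8 higher and 1 lower of 26, 11 and 2 adjusted over the list alone; median 0.57; camera adjusted p = 0.00367) and PPAR-alpha genes (10 higher and 0 lower of 42, the same adjusted over the list alone; median 0.40; camera adjusted p = 0.00339) passed camera. With an estimated correlation their adjusted p was 0.113 and 0.918. With the slide block limma called 0 genes of either list. NRF2-responsive genes then had a median of 0.33 (camera adjusted p = 0.0146, and adjusted p = 0.105 with an estimated correlation) and PPAR-alpha genes a median of 0.09 and a mean of -0.02 (camera adjusted p = 0.703). Acute phase genes, with a median of -0.17 over all arrays (camera adjusted p = 0.485), had -0.60 with the block (camera adjusted p = 2.29e-07, and adjusted p = 0.105 with an estimated correlation). Cell cycle genes (median 0.474, camera adjusted p = 0.000322) and hepatocyte markers (median -0.265, camera adjusted p = 0.0132) also passed with the block. With an estimated correlation their adjusted p was 0.962 and 0.264. The thiolase Acaa1b differed by 1.09 ± 0.187 and the acylcarnitine carrier Slc25a20 by 0.78 ± 0.137, and with the block by 0.68 ± 0.25 and 0.30 ± 0.148, not past the test (adjusted p 0.418 and 0.616). Median centring moved the share of higher calls from 33.3% to 67.5%, with a shift of 0.28 in the median of all genes. Ten1 missed the threshold without SD control 3 (adjusted p = 0.0673), and Por passed it without chimeric PB 4 (1.60 ± 0.561, adjusted p = 0.0465) or control 6 (1.70 ± 0.497, adjusted p = 0.0177).

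On control diet CAR KO rats differed from SD rats in 6035 of 17716 genes, 2546 higher and 3489 lower, with 992 at least 2-fold (863 higher, 129 lower). Each model lay on its own slide, so slide and model cannot be told apart. The oxidoreductase gene Oxnad1 was 10.2-fold higher in CAR KO rats (3 of 4 SD arrays measured it), Pcyox1l 6.46-fold, the purinergic receptor P2rx5 at least 4.41-fold, the glutamate-cysteine ligase subunit Gclm at least 4.0-fold and Chn1 at least 3.54-fold. Sdr16c6 (2.44 ± 0.705, 1 of 4 SD arrays), Raver2 (2.41 ± 0.328) and Hoxd12 (2.38 ± 0.422) were higher too. Ugt2b1 was lower by -2.36 ± 0.406 (adjusted p = 0.000544). Also lower were Mt2A (-2.22 ± 0.491), the phospholipase Pla2g2d (-2.13 ± 0.347), the retinol dehydrogenase Rdh16 (-2.01 ± 0.254), Ccdc152 (-2.004 ± 0.472), Fbxo27 (-1.92 ± 0.503, 1 of 4 CAR KO arrays) and Por (-0.73 ± 0.176, adjusted p = 0.0057). Cyp2b2 differed by -0.08 ± 0.138 (adjusted p = 0.687).

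By list, 11 of 25 unfolded protein response genes were lower and 1 higher in CAR KO rats (the same adjusted over the list alone; median -0.41; camera adjusted p = 0.0269, and adjusted p = 0.967 with an estimated correlation). Asparagine synthetase Asns was lower by -1.19 ± 0.167 and the chaperone Hsp90b1 by -0.79 ± 0.163. Of 17 hepatocyte markers 9 were lower (9 adjusted over the list alone; median -0.20; camera adjusted p = 0.0254, and adjusted p = 0.967 with an estimated correlation), Serpina1 by -0.40 ± 0.0607. Of 17 stellate cell markers 7 were lower and 1 higher (9 and 1 adjusted over the list alone; median -0.45; camera adjusted p = 0.111), and of 19 macrophage markers 4 were lower (2 adjusted over the list alone; median -0.39; camera adjusted p = 0.181). The stellate cell list averaged 0.44 ± 0.139 in SD and 0.13 ± 0.155 in CAR KO controls, and the macrophage list 1.81 ± 0.167 and 1.45 ± 0.341 (SD, n = 4 each). Conjugation enzymes had 12 lower and 1 higher of 38, acute phase genes 12 lower of 28 and pericentral genes 6 lower of 12, the same counts adjusted over the list alone, with camera adjusted p of 0.0754, 0.108 and 0.108. After normexp the share of higher calls was 27.5% in place of 42.2%, and with all 30 arrays in 1 fit, which called 2119 genes, it was 66.1%. Sdr16c6 missed the threshold without CAR KO control 4 or SD control 3 (adjusted p 0.0515 to 0.052).

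Chimeric livers on control diet differed from SD livers in 12788 of 17148 genes, 6632 higher and 6156 lower in chimeric mice, 6288 of them at least 2-fold (2505 higher, 3783 lower). The 2 models lay on different slides and scan days, and mouse RNA in the chimeric livers was not measured separately. The array is a rat design, and chimeric livers also hold cells of the mouse host. Host cells and cross-hybridisation are therefore part of this difference. A lower signal does not by itself show fewer cells or lower expression. The complement factor D gene (Cfd) was lower at least 265-fold, the leukocyte GTPase Rac2 at least 204-fold and the complement gene C1qc at least 165-fold, none measured on any chimeric control array. For beta-globin (Hbb) and the macrophage gene Aif1 no value is given, since the probe used was well above background on 0 chimeric control arrays and a second probe on all 7. The endothelial gene Plvap, measured on 1 of 7 chimeric arrays, was lower too (adjusted p = 5.95e-16). Higher in chimeric mice were the ribosomal protein-like gene Rps12l4 (at least 170-fold), Igfbp2 (67.6-fold), Hrh4 (67.4-fold) and Gpihbp1 (at least 63.5-fold). So were Clca5 (at least 23.9-fold), Ms4a8 (at least 21.8-fold), the mitochondrial arginase Arg2 (at least 17.9-fold) and Rnf186 (5.47 ± 0.731, 2 of 4 SD arrays).

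Of 18 macrophage markers 14 were lower and 2 higher in chimeric livers (median -1.75; camera adjusted p = 5.05e-06), and of 14 T, NK and B cell markers 11 were lower and 1 higher (median -2.11; 0.000895). Both had adjusted p = 0.341 with an estimated correlation. Of 14 endothelial markers 10 were lower and 1 higher (median -1.69; 0.000975), and of 17 stellate cell markers 13 and 4 (median -1.72; 0.00141), with adjusted p = 0.341 and 0.555 with an estimated correlation. Counts were the same adjusted over each list alone. These lower levels cannot tell fewer such cells from cells of the mouse host whose RNA the rat probes read poorly. With genes that no chimeric array measured set at their bound, the medians were -1.75, -1.65, -1.30 and -1.72. Tie1 of endothelium was at least 6.87-fold and the collagen gene Col5a1 at least 14.8-fold lower, whereas the capillary gene Gpihbp1, also on the endothelial list, was higher. The macrophage list averaged -1.18 ± 0.145 in chimeric controls (SD, n = 7) and 1.81 ± 0.167 in SD controls (SD, n = 4). Neutrophil markers had fewer than 5 tested members, so the list was not tested, and S100a9 (-3.53 ± 0.312, 2 of 7 chimeric arrays) and S100a8 (-2.67 ± 0.28, 1 of 7) were lower. Cholangiocyte markers went both ways, with 3 higher and 5 lower of 10 (camera adjusted p = 0.778): keratin 19 (Krt19) was at least 10-fold lower and osteopontin (Spp1) higher by 4.10 ± 0.405. Erythroid markers had 4 lower of 7 (median -0.83; camera adjusted p = 0.142) and hepatocyte markers 2 higher and 8 lower of 17 (median -0.21; camera adjusted p = 0.48).

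**Figure D3:**
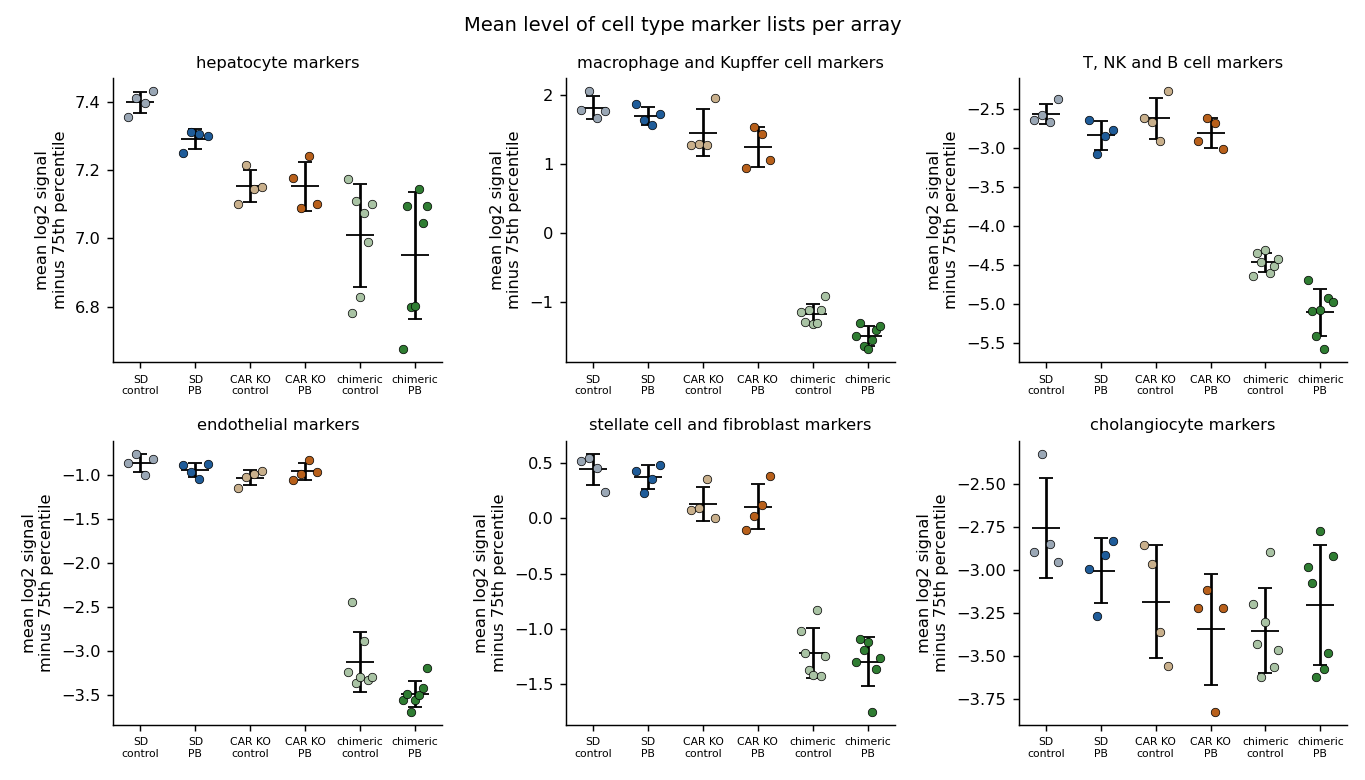
Mean log2 level of hepatocyte, macrophage, T, NK and B cell, endothelial, stellate cell and cholangiocyte marker lists on each array (vertical axis, relative to the array's 75th percentile) in the 6 groups. The macrophage list averages -1.18 in chimeric controls and 1.81 in SD controls, and the hepatocyte list 7.01 and 7.40.

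Of 26 cholesterol synthesis genes 16 were higher and 4 lower in chimeric mice on control diet (median 1.17; camera adjusted p = 0.00929, and adjusted p = 0.865 with an estimated correlation). Cyp51 stood at 2.08 ± 0.184. Of 42 PPAR-alpha genes 23 were higher and 4 lower (median 0.53; camera adjusted p = 0.0131, and adjusted p = 0.865 with an estimated correlation). The fatty acid carrier Cd36 stood at 2.87 ± 0.24. Of 23 lipogenesis genes 15 were lower and 2 higher (median -0.84; camera adjusted p = 0.0298, and adjusted p = 0.865 with an estimated correlation), and the carbohydrate-response factor Mlxipl stood at -2.47 ± 0.147. Of 34 interferon genes 20 were lower and 6 higher (median -1.29, and -0.97 with genes at their bound; camera adjusted p = 0.00902, and adjusted p = 0.629 with an estimated correlation). All counts were the same adjusted over the list alone, where over all genes 12788 of 17148 were called. Igfbp1 was higher by 4.51 ± 0.511. Of genes that PB raised in SD rats, Cyp2b2 was lower by -2.18 ± 0.245, and Cyp3a23-3a1 (1.46 ± 0.161), Ugt2b1 (1.88 ± 0.285) and Gadd45b (2.95 ± 0.389) were higher. The P450 gene Cyp1a2 was higher too (2.04 ± 0.167). The share of higher calls, 51.9%, was 68.2% after median centring, which moved the median of all genes by 0.40, and 69.8% after normexp; quantile normalization moved that median by 0.10.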

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

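The tests of slides 1 and 2, of slides 3 and 4, and of the CAR KO response against the chimeric response were chosen after the results they bear on had been seen; the other tests were written before.

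Differences between the PB responses of CAR KO and SD rats were tested directly, with the response in CAR KO rats minus that in SD rats given on the log2 scale. They stood past the threshold for Cyp2b2 (-4.12), Aldh1a1 (-3.70), Ces2c (-2.83), Gadd45b (-2.24), Cyp3a23-3a1 (-2.07), Por (-1.75), Ephx1 (-1.45) and Gins1 (-0.95). In the other direction stood Cpne4 (at least 2.01), Oat (1.61), Hal (1.07), Clybl (0.90) and Hsd17b2 (0.86). For chimeric mice minus SD rats the differences were at least 4.17 for Lpl, at least 1.78 for Tor4a, 4.29 for A1bg, 2.55 for Hdc, 2.40 for Ten1, 1.77 for the Cyp2b2 probe used, 1.09 for Acaa1b and 0.78 for Slc25a20. They were -4.36 for Vsir, -3.79 for Id3, -3.68 for Fscn1, -3.37 for Lrg1 and -3.32 for RT1-Da.

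In 15 of 265 pairs of a named gene and a group (5.66%), 1 array lay far from the others by Dixon's test, which marks about 1 in 20 groups by chance. In SD rats these were Cyp2b2 in control 2 (3.21, others averaging 2.86), Mlxipl in control 2 (1.03, others 1.43), Ces2j in control 3 (1.73, others 0.69), Cpt1a in control 4 (2.58, others 1.54), Serpina1 in control 4 (9.06, others 8.93), Dusp13b in PB 1 (-2.26, others -1.93) and Oat in PB 4 (4.50, others 3.77). In CAR KO rats they were Ces2c in control 3 (0.0364, others -0.40), Sdr16c6 in control 4 (-2.19, others -4.09) and Clybl in PB 3 (0.48, others 0.71). In chimeric mice they were Rnf186 in control 6 (3.37, others 0.00), Apol7b in PB 1 (-1.22, others -3.41), Slc25a20 in PB 1 (3.13, others 3.68), Ten1 in PB 4 (-1.51, others 0.22) and Ugt2b1 in PB 5 (7.38, others 7.97). No array had more than 2 such levels.

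The calls of the chimeric PB comparison lie across slides 1 and 2. A slide difference as the whole cause of the higher calls is argued against by the 312 genes higher in both chimeric mice and SD rats, whose diets shared a slide, where independent lists give 75.9. For the lower calls, 98 were lower in both against 55.4, under 2 times, the bound set for this test, and 10 against 0.967 with the slide block; overlap speaks only of genes called in SD rats (389 higher and 245 lower), so other calls stay open. Of the 3374 lower calls 44.4% lay in the dimmest of 3 equal classes of genes, and chimeric PB 1, on slide 1 with the controls, stood at -0.30 over them (log2 from the controls' mean, median over genes), against -0.89 to -1.24 for PB 2 to 7, arrays that also entered the calls. For the lower calls, slide, dim signal and PB cannot be told apart, since slide 1 holds 1 PB array. Macrophage markers had camera adjusted p = 0.046 over all arrays and 0.0348 with the slide block (adjusted p = 0.357 and 0.217 with an estimated correlation). T, NK and B cell markers had a median of -0.95 and endothelial markers of -0.19 (-0.71 and -0.31 with the block). Stellate cell, cholangiocyte and erythroid markers had medians of -0.00901, 0.0135 and 0.56 (-0.00414, -0.19 and 0.21 with the block). A loss of macrophages or of other such cells stays open, and these lists did not all fall alike. The lists cannot decide it, since the rat probes read the RNA of mouse host cells to an unknown degree.

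At least 2-fold higher calls of CAR KO against SD controls outnumbered lower ones, 863 to 129. Of the higher calls 61.3% lay in the dimmest of 3 equal classes, and 55% of the 129 lower calls lay there too. A high share was predicted for a signal difference between slides 3 and 4 that acts on dim spots. The classes were set by the mean of the SD controls, which are themselves part of this comparison. Genes higher in CAR KO rats thus fall among the dim ones in part by construction, so the share cannot decide on such a signal difference. On PB the same genes differed between the models by a median of 1.32, against 1.53 on control diet. Both diets of a model shared its slide, so this cannot tell slide from strain. The genetic difference between the models stays open as well and was not tested.

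The PB responses of SD and CAR KO rats correlated at 0.267 across genes, and in both models control diet lay in row 1 of the slide and PB in row 2. The row difference of the chimeric controls, measured on slide 1 over 14159 genes, correlated with the mean rat response at 0.061, under the bound of 0.1 set before, but by less than the spread of the 35 splits of these controls, 0.0434 (3 splits as large, the real one included, and 0.0776 as the highest other). The way this test was judged was changed after its value had been seen, to ask that the bound be met by more than the spread. The CAR KO response correlated at 0.379 with that of chimeric mice, whose diets each held 4 arrays in row 1 and 3 in row 2. Genes lower in both numbered 13 against 4.86 by independent lists, and 1 was higher in both against 0.773. The p of the former (Fisher's exact test, 0.00016) is a description, since genes are not independent. In the chimeric lower calls slide, dim signal and PB cannot be told apart, so this overlap does not argue against row. With slide and row as terms the correlation of the CAR KO and chimeric responses was 0.186, against -0.075 to 0.0412 with each control in the place of chimeric PB 1. That value rests on 1 array, and row effects of slides 3 and 4 were not measured. Row and a PB effect without CAR therefore cannot be told apart.

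Other splits of the same arrays argue against chance alone as the source of most counts, but cannot exclude it. Where there are 35 splits, the share of the real one is 1 of 35 at the least. A split that mixes the groups also adds their difference to the spread, which can lower its count. The real split was the 1 largest for PB in SD rats (732, highest other 5 of 35 splits), PB in CAR KO rats (36, highest other 2 of 35), PB in chimeric mice (6168, highest other 8 of 100), the difference between rat responses (95, highest other 3 of 100), CAR KO against SD controls (6035, highest other 3 of 35) and chimeric against SD controls (12788, highest other 10415 of 100). For the difference between chimeric and SD responses 2 of 100 splits were as large, the real one included. The other of these called 3693 against 3250, and the reason was not tested. With slide as a block 32 genes were called.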

How the results depend on the processing

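The slide 1 comparisons, the slide row block, the sets without 3 chimeric arrays and the slide, and slide and row, in the overlap were tests chosen after the data were seen. No named gene past its threshold changed direction past the threshold in any alternative, nor did a list in the alternatives counted for lists. Those were only part of the alternatives, without the slide blocks and without leaving out an array. The cause of a changed count was not tested, except that a stricter threshold calls fewer by construction. Signal over background limits the dim genes. With no filter on dim probes limma called 3520 genes in SD rats and 1706 in CAR KO rats, 83.3% and 77.7% of them higher. These counts include signals not well above background, and whether such calls are changes of expression was not tested.

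At an adjusted p under 0.01, counts were 212 in SD rats, 2 in CAR KO rats, 34 for the difference between rat responses, 1615 for that between chimeric and SD responses and 3693 for CAR KO against SD controls. At least 2-fold changes numbered 136, 14, 1866 in chimeric mice, 54, 1538, 992 and, for chimeric against SD controls, 6288. With all 30 arrays in 1 fit, counts were 200 in SD rats, 23 in CAR KO rats, 39 for the difference between rat responses and 2119 for CAR KO against SD controls. With only the arrays compared, they were 186 in SD rats and 0 in CAR KO rats by limma (3086 at an unadjusted p under 0.05). In CAR KO rats quantile normalization gave 17, the filter on every array 21 and array weights 325. Array weights gave 6439 for the difference between chimeric and SD responses.

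With slide as a block, chimeric PB calls numbered 158 and the difference from SD rats 32, with a random block 2561 and 489, and within slide 1 219 and 167. With slide row as a block 6128 chimeric calls were found. Without chimeric controls 2 and 4 and PB 4, which stand apart on the second principal component, counts were 6649, 4219 for the difference from SD rats and 12581 for the control diet. A slide block leaves the rat responses as they are and could not be fitted for the control diet comparisons, so it was not run there.

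Leaving out 1 array gave 396 to 685 genes in SD rats, 7 to 45 in CAR KO rats, 5578 to 6736 in chimeric mice, 64 to 110 for the difference between rat responses, 2620 to 4463 for that between chimeric and SD responses, 4942 to 5619 for CAR KO against SD controls and 11999 to 12873 for chimeric against SD controls.

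Genes higher in both SD rats and chimeric mice numbered 113 at an adjusted p under 0.01, 125 with all 30 arrays in 1 fit and 66 with the slide block, and genes lower in both 15, 19 and 10. For SD and CAR KO rats limma called 0 higher and 0 lower in both at 0.01, and 0 lower in both after quantile normalization.

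Lists called by camera with an estimated correlation numbered 3 in SD rats, 2 in CAR KO rats, 2 in chimeric mice, 1 for the difference between rat responses and 0 for the other comparisons. Fry called 2 in CAR KO rats, 15 in chimeric mice, 6 for the difference between rat responses, 13 for CAR KO against SD controls and 20 for chimeric against SD controls. For the difference between chimeric and SD responses quantile normalization gave 1 list and no filter 7; for CAR KO against SD controls normexp gave 0, quantile normalization 0 and all 30 arrays in 1 fit 5.

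The replicate number as a block gave 315 genes in SD rats, 3 in CAR KO rats and 25 for the difference between rat responses. Same-numbered arrays correlated from -0.14 to 0.0836 in SD rats, -0.284 to 0.146 in CAR KO rats and -0.22 to 0.83 in chimeric mice, and an array correlated best with its own number in 1 of 4, 1 of 4 and 3 of 7 pairs. Not every pair of any model lay above 0.1, the bound for taking numbers as pairs; chimeric pairs 4 to 7 lay at 0.26 or above, and the block gave 7045 chimeric calls.

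Over the alternatives other than leaving out 1 array, 2235 values of named genes kept their direction and side of the threshold, 193 lost and 5 gained a call. On leaving out 1 array 1892 kept it, 62 lost and 3 gained one. Of list values, whose alternatives here hold no slide block and no leaving out of 1 array, 1741 kept it, 89 lost and 74 gained one.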

Other observations

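Circadian clock genes went both ways in chimeric mice on PB. The clock output gene Dbp rose by 3.03 ± 0.907 (adjusted p = 0.0138, limma) and Per2 by 2.40 ± 0.658 (adjusted p = 0.00825), while Per1 was at least 1.85-fold lower, measured on 6 of 7 control arrays and no PB array. With slide as a block Dbp stood at 4.00 ± 1.86 (adjusted p = 0.48) and Per2 at 3.17 ± 1.35 (0.413), and Per1 did not pass either (0.766). The arrays within a group were far apart: Dbp lay at 5.53 in control 6 and at 0.89 in PB 2, where the other controls lay from 0.57 to 2.85 and the other PB arrays from 4.53 to 7.31. Of 14 clock genes 4 rose and 4 fell (5 and 4 adjusted over the list alone; median -0.19, mean 0.08; camera adjusted p = 0.87). On control diet CAR KO rats had Per3 higher by 1.06 ± 0.134 and Clock lower by -0.43 ± 0.0492 than SD rats. Time of sampling is not given in the sources used here.

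In chimeric mice on PB Stac3, from the male-predominant list, fell by 2.92 ± 0.525 (adjusted p = 0.000463), and stood at -3.11 ± 1.09 with slide as a block (adjusted p = 0.279). Carbonic anhydrase 3 (Car3), also on that list, fell by 1.18 ± 0.234 on PB in SD rats (adjusted p = 0.0117) and was lower by -1.42 ± 0.235 in CAR KO than in SD controls. Between these controls 2 male-predominant genes were higher and 5 lower of 20 (2 and 6 adjusted over the list alone; camera adjusted p = 0.399), with Akr1c13 higher by 1.09 ± 0.292. Of 17 female-predominant genes 5 were higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.398).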
